A study of Homo sapiens with 4 samples.

How the data were processed

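HiChIP for H3K27ac was performed on 4 breast carcinoma cell lines. Per the labels' protocols, cells were grown without estrogen for 3 days and treated with 10 nM estradiol for 45 minutes. Proximity ligation with biotin, sonication, immunoprecipitation, biotin capture and a Tn5 library of 11 PCR cycles followed. Sequencing was on an Illumina NovaSeq6000. Groups were taken from the cell line in the labels and the histology given in the series' design text: ductal (MCF7 as replicate 1, T47D as replicate 2) and lobular (MDA134 as replicate 1, SUM44 as replicate 2). Each line had 1 library, so the replicate is the cell line and p-values measure the spread between lines. Replicate numbers only name samples and pair none.

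Per the submitters' processing notes, BWA, MACS2 and HiC-Pro were used, with the hg19 build, and no versions were named. The tool that called the loops was not given in the sources used here. The deposited lists hold pairs of 5 kb bins with the contact count of each pair and the coverage of both bins, which are raw counts by their values. The deposited relative coverage of a bin is a ratio, its coverage over the mean coverage of its class of bins (in a peak or not), as checked on the values. Peaks are marked by 0 or 1. The authors' expected contact count, and the model probabilities deposited as fractions, come from a model of distance and coverage. The p-value and q-value per pair are the authors' own, and every listed q-value was below 0.01, so pairs that did not pass are not listed. The expected count divided by the model probability gave 1 constant per list, which was taken as the number of contacts modelled: 21482636 in MCF7, 11277516 in T47D, 9994061 in MDA134 and 14932193 in SUM44. The lists differ in length and depth, and copy number was not corrected.

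The files use hg19: 0 loops lay beyond the ends of its chromosomes. The gene table used here is of the assembly GRCh38.p14, so none of its coordinates were used and no loop was assigned to a gene. For this reason 4 results fixed beforehand could not be computed: promoter contact counts per gene, the 14 gene lists, genes with a promoter loop in 1 histology, and loops at the FOXA1 promoter. In their place, loops were counted per chromosome band with the hg19 bands of circlize 0.4.16, a choice made after the files were seen. A loop counts for a band if at least 1 anchor's centre lies in it. The 12 genes fixed to be named appear through the band they lie in, from general knowledge. The bands 3q29, 16q12.2, 17q22 and others beyond these and the 4 fixed regions (8p11-p12, 11q13, 17q23 and 20q13) were chosen after their values were seen. Regions of high coverage were 8p11-p12, 11q13, 16q12, 17q22, 17q23 and 20q13. This name is used for the same regions in every line, although which of them was highly covered differed between lines.

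Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for counts, and matplotlib 3.10.9 for figures. Shares have 95% Wilson intervals, which cover counting error only, since PCR reads without molecular identifiers and loops of neighbouring bins are not independent. Differences between histologies were tested by exact 2-sided permutation over the 6 assignments of the lines. Loops of 2 lists matched where both anchors overlapped or adjoined, and overlap was the number of matched loops of both lists over all loops of both. Its test was an exact 1-sided permutation over the 3 ways to part the lines into pairs. Loops of 1 pair only were loops of the shorter list with a match in the other line and none in the remaining lines. The match rule was tested on 2000 simulated loops.

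Contact counts of the 153 loops called with identical bins in all 4 lines were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, lobular against ductal, with TMM factors on these loops and Benjamini-Hochberg adjustment. In simulated counts with the same means and library sizes, 20 of the 153 loops were changed. All simulated loops had the same dispersion, 0.144, and were drawn independently. Loops of the data share anchors, so the rates that follow may not hold for them. The test recovered 0% of them at a 4-fold change, 90% at 6-fold and 100% at 8-fold, with 0 false calls. Alternatives used DESeq2 1.42.0 and limma 3.58.1. Loops are named by a rule: the 5 per direction with the largest fold among those past the threshold whose 2 lines of 1 histology lie above both others, filled up by smallest p where fewer passed. A test of contact sums per band, added after the data were seen, called 0 of 499 bands in edgeR, with 88 at an unadjusted p below 0.05, and with DESeq2 4 bands higher in lobular and 45 higher in ductal lines. It also recovered 0% of 60 bands changed 64-fold in simulated counts, so it is not used further.

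Alternatives for the lists were q-values under 0.001 and 0.0001, identical bins, a gap of up to 5000 bp, equal list length (the 2130 loops of lowest q per line), leaving out chromosomes 8, 11, 17 and 20, and leaving out each line. Alternatives for the counts were other size factors and library sizes, DESeq2, a minimum mean count of 10, loops of at least 2 lines, and the ratio of observed to expected contacts.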

Results

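Contacts of chromatin marked by H3K27 acetylation, a histone mark of active promoters and enhancers, were measured by HiChIP in 4 breast carcinoma cell lines. MCF7 and T47D are lines of ductal carcinoma, and MDA134 (MDA-MB-134) and SUM44 (SUM44PE) are lines of lobular carcinoma. All 4 lines were kept without estrogen for 3 days and then given 10 nM estradiol for 45 minutes, so the comparison is between histologies, and no untreated library was analysed here. There was 1 library per line, and the line was the replicate, with n = 2 per histology. A called loop was a pair of 5 kb bins on 1 chromosome with more contacts than the authors' model predicted, at a q-value below 0.01. The 4 loop lists rested on 21482636 modelled contacts in MCF7, 11277516 in T47D, 9994061 in MDA134 and 14932193 in SUM44. With 2 lines against 2, the smallest exact permutation p is 0.333, so no single value could pass 0.05.

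The first comparison asked how many loops each line had and how far they reached. MCF7 had 10930 loops, T47D 2967, MDA134 2130 and SUM44 3892. Per 1000000 modelled contacts, these were 509 loops in MCF7, 263 in T47D, 213 in MDA134 and 261 in SUM44, so MCF7 stood apart from T47D by more than the histologies did. The mean was 386 ± 174 loops per 1000000 contacts in ductal lines and 237 ± 33.6 in lobular lines (SD, n = 2 each), with an exact 2-sided permutation p of 0.333. Loops spanned a median of 195 kb in MCF7, 160 kb in T47D, 150 kb in MDA134 and 205 kb in SUM44, and the group means were 177.5 kb in both histologies. Both anchors lay in acetylation peaks for 65.2% of MCF7 loops (95% Wilson interval 64.3 to 66.1), 76.6% of T47D loops (75.02 to 78.06), 80.0% of MDA134 loops (78.2 to 81.6) and 74.9% of SUM44 loops (73.5 to 76.2). These intervals cover counting error only. A median loop held 25 contacts in MCF7, 24 in T47D, 22 in MDA134 and 23 in SUM44. The exact permutation test was run on 5 measures, with a lowest Benjamini-Hochberg adjusted p of 0.833. They were the number of loops, loops per 1000000 contacts, median span, share with both anchors in peaks and median observed over expected contacts. The contacts of a median loop were not tested.

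The second comparison asked where on the chromosomes the loops of each histology lay. In both lobular lines, loops were concentrated on 8p11-p12 and 11q13, regions that are often gained in breast cancer. The region 8p11-p12, which holds FGFR1, a growth factor receptor gene, and ZNF703, a luminal transcription factor gene, had 488 of the 2130 MDA134 loops (22.9%, 21.2 to 24.7) and 440 of the 3892 SUM44 loops (11.3%, 10.35 to 12.34). It had 117 of the MCF7 loops (1.07%, 0.894 to 1.28) and 21 of the T47D loops (0.708%, 0.463 to 1.08). The region 11q13, which holds the cyclin D1 gene CCND1, had 15.4% of MDA134 loops and 10.7% of SUM44 loops, against 1.56% of MCF7 loops and 1.62% of T47D loops. The lobular mean exceeded the ductal mean by 16.2 percentage points on 8p11-p12 and by 11.4 on 11q13. Without lobular replicate 1, MDA134, the excess on 8p11-p12 was 10.4 percentage points. Both lobular lines lay above both ductal lines, with an exact 2-sided permutation p of 0.333 for each region, the smallest possible, and 0.444 after Benjamini-Hochberg adjustment over 4 regions. The 4 regions had been fixed beforehand as gene lists, but the test of their shares was chosen after the files were seen. On 8p11-p12 and 11q13, anchor bins outside peaks were covered more deeply in the lobular lines than their anchor bins elsewhere. On 8p11-p12 the ratio of median coverage was 7.13 in MDA134 and 4.36 in SUM44, against 0.63 in MCF7 and 0.977 in T47D. The medians of the region rested on 184 bins in MDA134, 158 in SUM44, 44 in MCF7 and 10 in T47D.

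**Figure D1:**
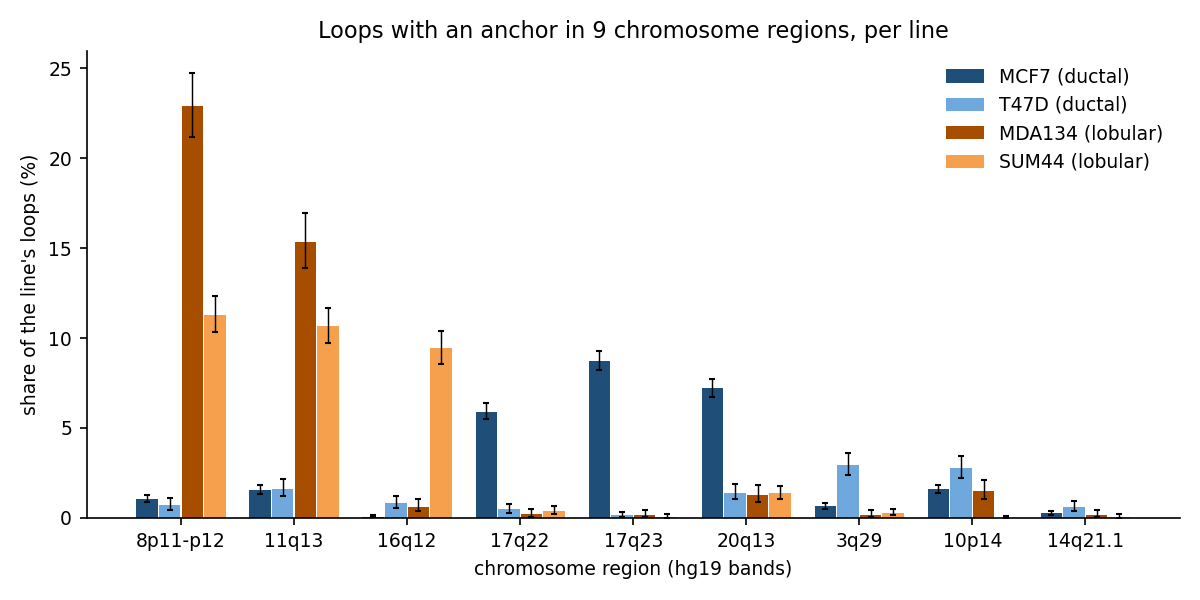
Share of each line's loops (percent, vertical axis) with an anchor in 9 chromosome regions (horizontal axis), with 95% Wilson intervals for counting error as error bars. The lobular lines MDA134 and SUM44 stand highest on 8p11-p12 (22.9% and 11.3%) and 11q13, and MCF7 alone is high on 17q22, 17q23 and 20q13.

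Within 8p11-p12, most loops of the lobular lines lay in 8p11.23, with 382 in MDA134 and 423 in SUM44 against 79 in MCF7 and 13 in T47D. A single bin there, at 37,550,001 to 37,555,000 on chromosome 8, was an anchor of 133 loops in MDA134, 125 in SUM44, 46 in MCF7 and 7 in T47D. On 11q13.3, the band of CCND1, MDA134 had 258 loops, SUM44 206, MCF7 69 and T47D 8. The other regions fixed beforehand were high in MCF7 but not in T47D. On 17q23, MCF7 had 956 loops (8.75%), T47D 4, MDA134 3 and SUM44 2. On 20q13, MCF7 had 788 loops (7.21%), against 1.38% of the loops in T47D, 1.27% in MDA134 and 1.36% in SUM44. The exact 2-sided permutation p was 0.667 for 17q23 and 0.333 for 20q13, with n = 2 per histology.

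Further regions were noticed only after the loops had been counted. In SUM44, 16q12.2 had 367 loops (9.43%, 8.55 to 10.4), against 13 in MDA134, 23 in T47D and 7 in MCF7. In T47D, the first-ranked band was 3q29, with 87 loops (2.93%, 2.38 to 3.60), against 69 in MCF7, 3 in MDA134 and 11 in SUM44. In MCF7, the band 17q22 had 646 loops (5.91%, 5.48 to 6.37).

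The bands that hold genes of luminal and estrogen-responsive breast cells were compared next, with genes named for the band alone, since no loop was assigned to a promoter. In the band of GATA3, a luminal transcription factor gene, at 10p14, MCF7 had 174 loops, T47D 82, MDA134 32 and SUM44 0. As a share of loops outside the regions of high coverage (8p11-p12, 11q13, 16q12, 17q22, 17q23 and 20q13), 10p14 had 1.97% in MCF7 (95% Wilson interval 1.70 to 2.29), 2.91% in T47D (2.35 to 3.60) and 2.52% in MDA134 (1.79 to 3.54), so MDA134 lay between the ductal lines. The band of ESR1, the estrogen receptor gene, at 6q25.1, had 36 loops in MCF7, 16 in T47D, 3 in MDA134 and 4 in SUM44. As a share of loops outside the same regions, 6q25.1 had 0.408% in MCF7, 0.568% in T47D, 0.237% in MDA134 and 0.154% in SUM44. The band of the progesterone receptor gene PGR, 11q22.1, had 44 loops in T47D and 1 in MCF7, and none in the lobular lists. The band of MYC, a proliferation gene, at 8q24.21, had 48 loops in MCF7, 24 in T47D, 9 in MDA134 and 16 in SUM44, which was 0.544%, 0.853%, 0.710% and 0.615% of the loops outside the same regions. The band of CDH1, the E-cadherin gene that lobular carcinomas commonly lose, at 16q22.1, had 34 loops in MCF7, 6 in T47D, 1 in MDA134 and 10 in SUM44 (0.386%, 0.213%, 0.0789% and 0.385% outside these regions). The estrogen-responsive genes GREB1 and TFF1 lie in 2p25.1 and 21q22.3. The band 2p25.1 had 28 loops in MCF7, 16 in T47D and 10 in each lobular line, or 0.318% in MCF7, 0.568% in T47D, 0.789% in MDA134 and 0.385% in SUM44 outside these regions, with no order by histology. The band 21q22.3 had 66 in MCF7, 9 in T47D, 8 in MDA134 and 17 in SUM44 (0.748%, 0.320%, 0.631% and 0.654%). In 22q12.1, the band of the secretory stress gene XBP1, the counts were 11 in MCF7, 7 in T47D, 6 in MDA134 and 11 in SUM44, and the shares of both lobular lines (0.473% and 0.423%) lay above those of MCF7 (0.125%) and T47D (0.249%), but only MCF7 and SUM44 had intervals that did not overlap. In 6p12.3, the band of TFAP2B, MCF7 had 4 loops and MDA134 6, with none in the lists of T47D and SUM44.

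The series concerns FOXA1, a pioneer factor that opens chromatin for the estrogen receptor, in lobular carcinoma, and its band 14q21.1 was examined. The ductal lines had 28 loops (MCF7) and 18 loops (T47D) with an anchor there, and the lobular lines had 3 (MDA134) and 2 (SUM44). This was 0.318% of MCF7 loops outside the regions of high coverage (95% Wilson interval 0.220 to 0.459), 0.639% of those of T47D (0.405 to 1.01), 0.237% of those of MDA134 (0.0805 to 0.693) and 0.0769% of those of SUM44 (0.0211 to 0.280). Both ductal lines lay above both lobular lines, with an exact 2-sided permutation p of 0.333. Of the 4 pairs of a ductal and a lobular line, only T47D and SUM44 had intervals that did not overlap. In T47D, 17 of the 18 loops joined the same 2 stretches of neighbouring bins, described below. The intervals treat such loops as independent, so they are too narrow. A set of ductal loops was not called in either lobular line. These loops joined bins between 38,000,001 and 38,100,000 on chromosome 14 (hg19) to bins between 37,600,001 and 37,800,000, in 13 loops of MCF7 with 335 contacts in all and in 17 loops of T47D with 417 contacts in all. The pair of them with the most contacts in MCF7, at 37,720,001 and 38,060,001, held 51 contacts there, 11.5 times its expected count, and 34 contacts in T47D, 9.26 times its expected count. Both lobular lines instead had a loop of 50 kb from 38,065,001 to 38,070,000 to 38,115,001 to 38,120,000, with 33 contacts in MDA134 and 35 in SUM44. Its expected count was 8.25 in MDA134 (q-value of 4.1e-07) and 14.6 in SUM44 (q-value of 0.00563). This loop was not called in MCF7 or T47D. Called loops of 50 kb held a median of 41 contacts in MCF7 (lowest 10) and 39.5 in T47D (lowest 15). Calling depends on the expected count of a pair, which is not listed for this pair in the ductal lines. These values therefore set no floor for its contacts there. Of the loops of the band, 23 in MCF7, 17 in T47D, 2 in MDA134 and 2 in SUM44 had an anchor between 38,000,001 and 38,100,000. The others lay between 39,570,001 and 39,905,000. Among them, the loop from 39,640,001 to 39,900,001 was called in MCF7 (24 contacts) and in MDA134 (14 contacts). The other SUM44 loop, from 38,050,001 to 38,340,001, lay near an MCF7 loop from 38,060,001 to 38,340,001. At equal list length, MCF7 had 10 loops in 14q21.1 and SUM44 had 0. A pair of bins missing from a list has an unknown count, so a loop not called in a line is not shown to be absent from it.

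**Figure D2:**
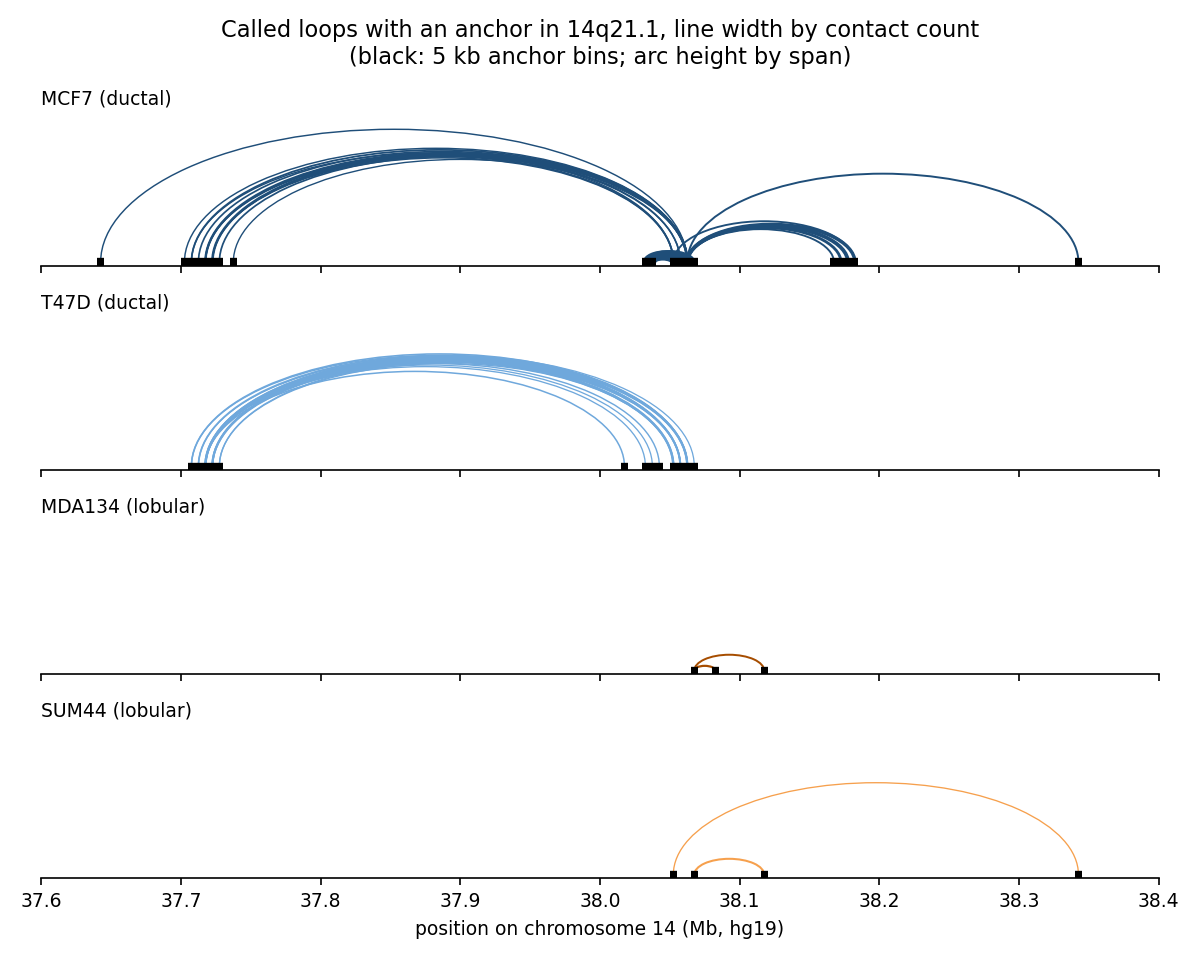
Called loops with an anchor in 14q21.1 between 37.6 and 38.4 Mb of chromosome 14 (horizontal axis, hg19), 1 panel per line, as arcs whose width grows with the contact count, between 5 kb anchor bins drawn in black. The ductal lines MCF7 and T47D have 13 and 17 loops from 38.0 to 38.1 Mb back to 37.6 to 37.8 Mb, and the lobular lines have none of these.

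The third comparison asked whether the lines of 1 histology shared more loops with each other than with the lines of the other. Loops matched where both anchors overlapped or adjoined. The lobular pair shared 34.7% of the loops of both lists (95% Wilson interval 33.5 to 35.9) and the ductal pair 28.3% (27.6 to 29.1), and the 4 mixed pairs shared between 18.2% and 23.99%. The mean overlap within histologies exceeded that between them by 10.8 percentage points. This was the highest of the 3 ways to part the 4 lines into pairs (exact 1-sided permutation p of 0.333, the smallest possible). Without chromosomes 8, 11, 17 and 20, the overlap of the lobular pair was 23.1%, within the range of 17.2% to 24.7% of the mixed pairs. That of the ductal pair was 30.9%, and the excess within histologies fell to 5.86 percentage points. Across all 4 lines, 324 of the 2130 loops of MDA134 had a match in each of the others (15.2%).

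**Figure D3:**
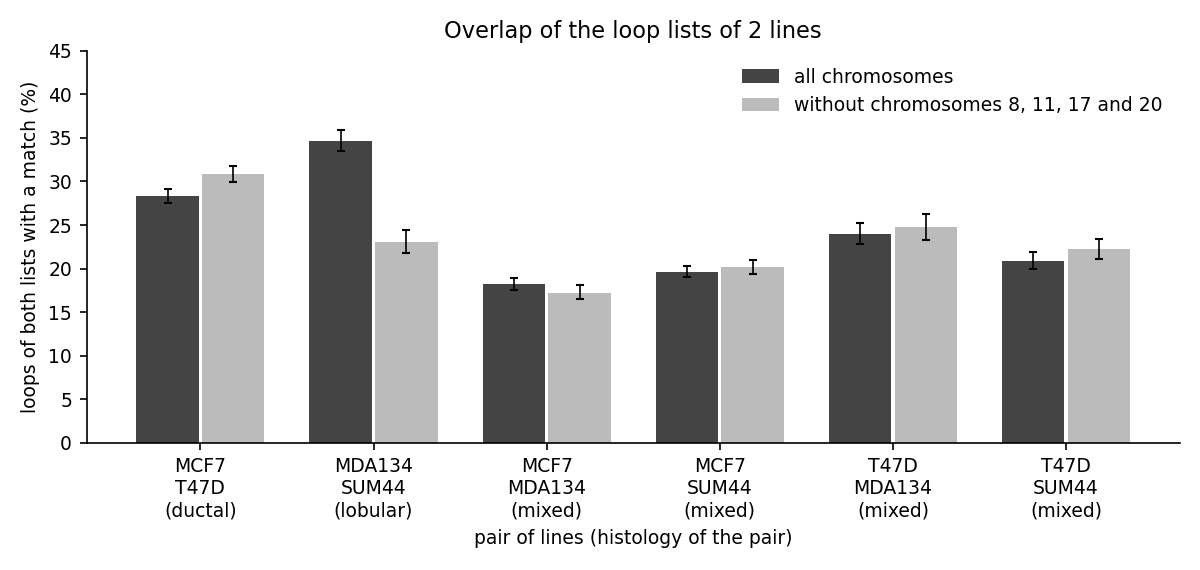
Share of the loops of both lists of a pair that had a match in the other list (percent, vertical axis) for the 6 pairs of lines (horizontal axis), over all chromosomes (dark bars) and without chromosomes 8, 11, 17 and 20 (light bars), with 95% Wilson intervals. The lobular pair drops from 34.7% to 23.1%, and the ductal pair stands at 28.3% and 30.9%.

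Loops found in both lines of a histology and in neither line of the other numbered 953 for the ductal pair and 312 for the lobular pair. The mixed pairs had 268, 438, 57 and 115 such loops. Of the 312 lobular loops, 228 (73.1%) had an anchor on 8p11-p12 or 11q13, and 158 of them lay in 8p11.23. The remaining 84 lay outside both regions. Of the 54 of these with identical bins in both lines, the strongest relative to depth joined neighbouring bins in 22q12.1, the band of XBP1. It ran from 29,210,001 to 29,220,000 on chromosome 22, with 203 contacts in MDA134 and 193 in SUM44. The ranking did not correct for span, and the loops next in it also joined neighbouring bins. The contacts of this pair of bins in MCF7 and T47D are unknown, as it was not called there. Loops from the bin at 29,195,001 to each of its bins were called in every line. Their normalised contacts were higher in both ductal lines, with log2 fold changes of -0.94 and -0.70 (adjusted p of 0.348 and 0.506 in edgeR). Of the 953 ductal loops, 45 had an anchor in 10p14, the band of GATA3, and 36 in 3q29, followed by 17 in 3q27.1 and 14 each in 14q21.1 and 21q22.2. In 10p14, MDA134 had 32 loops and SUM44 had 0, so only the calls of MDA134 could take a loop there out of this set. At equal list length, the ductal pair had 266 and the lobular pair 399. Without ductal replicate 1, MCF7, the lobular pair had 599 loops not matched in T47D.

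The fourth comparison tested the contact counts of the 153 loops called with identical bins in all 4 lines, the only loops with a count in every library. Lobular lines were higher for 11 loops and ductal lines for 0 in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, with 37 loops at an unadjusted p below 0.05. All 11 lay on 8p11-p12 (7 loops) or 11q13 (4 loops), with log2 fold changes between 1.89 and 3.49. Neighbouring pairs of bins were tested without merging. Most of the 7 loops shared the anchor bin at 37,550,001. The 4 loops on 11q13 all joined bins between 68,870,001 and 68,895,000 to bins between 69,450,001 and 69,490,000. The 11 loops are thus not 11 separate contacts. Of the 5 with the largest fold, 3 lay in 11q13.3 and 2 in 8p11.23. A loop in 11q13.3, from 68,890,001 to 68,895,000 to 69,450,001 to 69,455,000, held 24 contacts in MCF7, 15 in T47D, 176 in MDA134 and 64 in SUM44. Its log2 fold change was 3.49 ± 0.76 (SE, n = 2 lines per histology, adjusted p of 0.0185 in edgeR). A loop in 8p11.23, from 37,240,001 to 37,245,000 to 37,550,001 to 37,555,000, held 15, 18, 85 and 99 contacts in the same order of lines. Its log2 fold change was 3.18 ± 0.68 (adjusted p of 0.0185 in edgeR). The other 3 of the 5 had log2 fold changes of 3.13, 2.88 and 2.78. Without lobular replicate 1, MDA134, the 3 named loops of 11q13.3 had log2 fold changes of 2.17, 1.91 and 1.54, in place of 3.49, 3.13 and 2.78, and those of 8p11.23 had 2.93 and 2.35, in place of 3.18 and 2.88. Over the 136 loops outside both regions, the median log2 fold change was -0.09 and none passed in edgeR, with 21 at an unadjusted p below 0.05.

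Among loops with more normalised contacts in both ductal lines, none passed the threshold in edgeR. The 5 of smallest p had log2 fold changes between -1.81 and -2.07. Leading them was a loop in 17q21.33, from 48,940,001 to 49,025,001 on chromosome 17, with 723 contacts in MCF7, 263 in T47D, 63 in MDA134 and 82 in SUM44 (log2 fold change of -1.87 ± 0.60, SE, edgeR adjusted p of 0.0824). The others lay in 11q13.1, 2p25.1, 3q25.31 and 11q23.3. In limma on contacts over their expected count, these 4 turned direction, with log2 fold changes of 0.62, 0.12, 0.59 and 0.57, and the loop in 17q21.33 had one of -0.25. The split of calls depended on the scaling. It was 14 higher in lobular and 5 higher in ductal lines with the size factors of DESeq2, 11 and 6 in the Wald test of DESeq2, and 7 and 6 with all modelled contacts as library size. No call was left in limma on the ratio of contacts to the authors' expected count, which takes in the coverage of both anchors. The 5 named lobular loops had log2 fold changes between 1.35 and 1.95 there, in place of 2.78 to 3.49 in edgeR. None of the 11 loops passed when the 2712 loops of at least 2 lines were tested with 0 where not called. The 5 named ones had log2 fold changes between 2.62 and 3.32 there. The zeros stand for unknown counts and enter the spread that this fit estimated, so it cannot decide on the 11 loops. Leaving out a line left 1 library in its histology, so the spread came from the other 2 lines alone. There were then 0 calls in edgeR without MCF7, without MDA134 and without SUM44, and 11 higher in lobular and 3 higher in ductal lines without T47D. Of these 14 calls, only 5 were among the 11 loops called with all lines, and only 7 lay on 8p11-p12 or 11q13. The 5 named lobular loops had log2 fold changes between 2.54 and 3.41 without MCF7 and between 3.07 and 4.03 without SUM44. As they were chosen for having both lobular lines above both ductal lines, leaving out a line could hardly turn their direction.

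**Figure D4:**
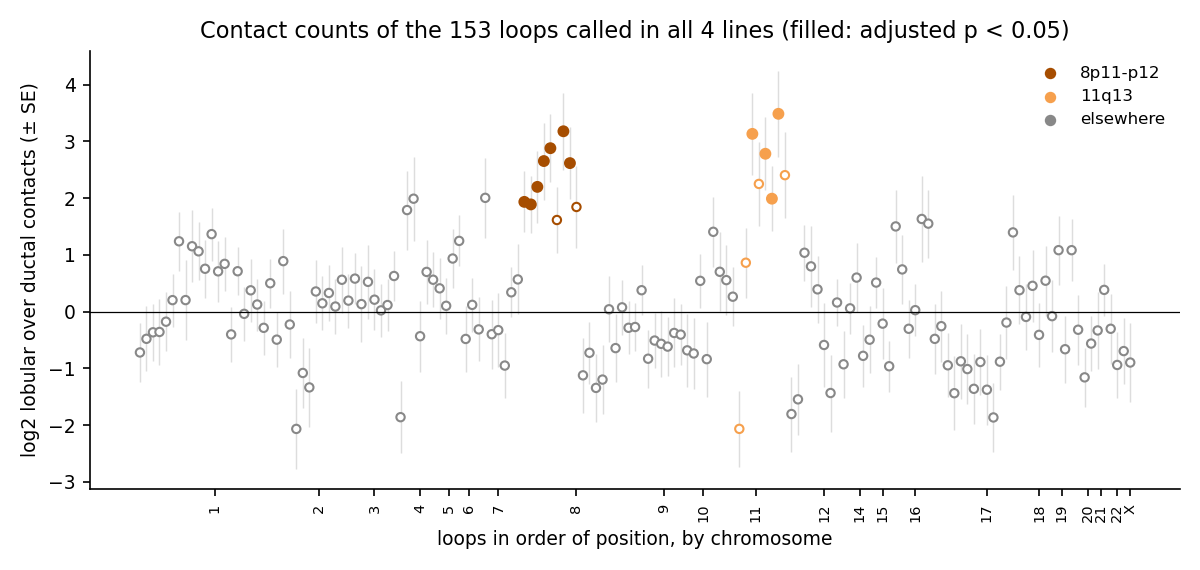
Log2 fold change of lobular over ductal contacts with its SE (vertical axis) for the 153 loops called in all 4 lines, in order of position by chromosome (horizontal axis), with filled points at an adjusted p below 0.05. The 11 filled points all lie on 8p11-p12 (dark orange) or 11q13 (light orange), between 1.89 and 3.49.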

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

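Alternatives were fixed before the data were examined, except all modelled contacts as library size, equal list length combined with leaving out chromosomes, and all alternatives for shares of loops per region and for contact sums per band. The gene-level alternatives (promoter windows, gene lists, genes with a promoter loop) were not run, as no loop was assigned to a gene, and neither was the wider FOXA1 promoter window. No paired analysis was possible because replicate numbers only name the lines. A minimum mean count of 10 removed none of the 153 loops, so it tested nothing. No alternative varied the depth of the libraries, so its effect on the lists was not measured. At q under 0.0001 the lists held 5680 (MCF7), 1429 (T47D), 1052 (MDA134) and 1798 (SUM44) loops, and SUM44 had 2543 at q under 0.001. The excess of overlap within histologies kept its sign under the alternatives run for it, which did not include q under 0.0001. It was 5.86 percentage points without chromosomes 8, 11, 17 and 20, against 10.8 with all chromosomes. The overlap of the lobular lists was 23.05% with identical bins, 38.8% with a gap of up to 5000 bp, 36.5% at equal list length, 23.1% without chromosomes 8, 11, 17 and 20 and 22.6% with both of the latter; the drop follows from the chromosomes left out. Loops of both ductal lines only numbered 266 at equal list length and 148 with those chromosomes also left out, and loops of both lobular lines only numbered 72 without the chromosomes and 68 with both. Leaving out 1 ductal line gave between 353 and 599 lobular loops. The lobular excess on 8p11-p12 was 17.3 percentage points at equal list length and 18.4 at q under 0.001, and between 10.4 (without MDA134) and 22.02 (without SUM44) when 1 line was left out. On 11q13 it was 12.2 and 13.7, and between 9.08 and 13.8. In 14q21.1, MCF7 had 10 loops at equal list length, and SUM44 had 0 both there and at q under 0.001. For the loops called in all 4 lines, calls higher in lobular and ductal lines were 7 and 0 with the contacts of the deposited list as library size, 7 and 6 with all modelled contacts, 14 and 5 with DESeq2 size factors, and 11 and 6 in the DESeq2 Wald test, in which 18 loops had no adjusted p. They were 318 and 776 when loops of at least 2 lines entered with 0 where not called (none of them among the 11, with log2 fold changes of the 5 named lobular loops between 2.62 and 3.32 and adjusted p between 0.0675 and 0.178), 0 and 0 in limma on observed over expected, and 0 and 0 without the 4 chromosomes, which hold all the calls. Leaving out each line gave between 0 and 11 calls higher in lobular and between 0 and 3 higher in ductal lines, and the highest numbers, without T47D, held 5 of the 11 loops and 7 loops on 8p11-p12 or 11q13. These scalings moved the median log2 fold change of all 153 loops by 0.14 (DESeq2), 0.37 (contacts of the list) and 0.43 (all modelled contacts). The 5 named lobular loops stayed higher in lobular lines in all 50 values of the alternatives that changed the test. They were chosen for having both lobular lines above both ductal lines, so a kept direction is no support for them. None of the 5 passed in limma on observed over expected contacts (adjusted p between 0.103 and 0.184). Of the named ductal loops, 4 reversed in limma on observed over expected, to log2 fold changes of 0.62 (11q13.1), 0.12 (2p25.1), 0.59 (3q25.31) and 0.57 (11q23.3); the cause was not tested.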

Other observations

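Tests of explanations here were chosen after the values they concern had been seen, except 3 alternatives fixed beforehand, whose bounds were written afterwards: overlap at equal list length, overlap without 4 chromosomes, and limma on observed over expected contacts. Both lobular lines shared a leading bin, in 8p11.23, which ranked first in MDA134 and second in SUM44. The next bins of MDA134, in 8p11.23 and 11q13.3, had 59 and 43 loops there and 47 and 28 in SUM44. In MCF7 a bin in 20q13.2, at 52,820,001 to 52,825,000 on chromosome 20, was an anchor of 139 loops, against 7 in T47D, 0 in MDA134 and 1 in SUM44, and a bin in 17q23.1, at 57,920,001 on chromosome 17, was an anchor of 104. In SUM44 a bin in 16q12.2, at 54,960,001 to 54,965,000 on chromosome 16, was an anchor of 183 loops (4.70% of its list), against 2 in MCF7, 9 in T47D and 7 in MDA134. A bin in 11q13.5, at 76,495,001 on chromosome 11, was an anchor of 65 loops in SUM44, of 9 in MDA134 and of none in the ductal lists. In T47D the leading bins lay in 3q29 (39 loops), in 8q23.3 (27 loops), the band of the luminal factor gene TRPS1, and in 10p14 (24 loops), and MCF7 had 13, 14 and 47 loops at the same bins.

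Loops pooled over the regions of high coverage reached farther in 3 of the 4 lines. Spans over 1 Mb made up 18.3% of these loops in MCF7 (95% Wilson interval 16.73 to 20.03), against 3.36% of its other loops. The shares were 8.005% and 2.37% in MDA134 and 11.4% and 1.65% in SUM44. In MDA134, 68 of the 69 such loops lay on 8p11-p12, 65 of them with an anchor in 8p11.21, and 11q13 had 1 of 327 (0.306%), below the share elsewhere. In MCF7, 8p11-p12 and 11q13 had 0, and neither was highly covered there (coverage ratios of 0.63 and 0.97). In T47D, whose list had 152 loops in the pooled regions, the shares were 1.32% and 3.55%. The pooled regions were not all highly covered in T47D. Its non-peak anchor bins had median relative coverage of 2.83 on 8p11-p12, 2.42 on 20q13 and 2.30 on 16q12, against 2.89 elsewhere. The medians of 11q13, 17q23 and 17q22 were higher but rested on 3, 2 and 1 bins. Within 11q13.5, 46 of the 108 SUM44 loops spanned over 1 Mb (42.6%).

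The concentration of lobular loops on 8p11-p12 and 11q13 was weighed against coverage, list length and depth. List length is argued against by the difference on 8p11-p12 at equal list length, which was 17.3 percentage points. Depth stays open, as no alternative varied it and each line had 1 library. The shares did not go 1 way with depth: T47D lay between the lobular lines in modelled contacts and SUM44 between the ductal lines. In both regions, the intervals of T47D and SUM44 were at least 7.59 percentage points from those of the lines next to them in depth, but these intervals cover counting error only. Coverage remains a candidate explanation. The lowest ratio of non-peak anchor coverage in these regions to elsewhere was 2.42 in the lobular lines, as a gain in copy number would give. The highest ratio in the ductal lines was 1.30. The ratio of 2.42 (SUM44 on 11q13) rested on 52 bins of the region, and that of 1.30 (T47D on 11q13) on only 3. Anchors are bins that already carry a loop, and copy number itself was not measured. Whether contacts were stronger than coverage accounts for stays open: over the 17 loops of these regions called in all 4 lines, the median log2 fold change was 2.25 for contacts and 0.91 for contacts over their expected count, with 0 calls in limma (15 of the 153 loops at an unadjusted p below 0.05).

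The high overlap of the 2 lobular lists may come from these same regions. Without chromosomes 8, 11, 17 and 20 it was 23.1%, below the highest mixed pair at 24.7%, whereas the ductal pair stood at 30.9%. Unequal list length is argued against by an overlap of 36.5% at equal list length, against at most 23.9% in mixed pairs. The 11 loops with higher lobular contacts came from 1 of 3 splits of the lines, and the highest other split gave 0, but 3 splits are too few for a share under 0.05.

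SUM44 had no called loop in 10p14, the band of GATA3, although MDA134 had 32 and T47D 82 with fewer modelled contacts. Depth or list length is argued against, since 58.5 loops would be expected at the lowest share of the other 3 lines. Loss of the whole short arm is argued against by 36 SUM44 loops on 10p outside the band. No anchor of SUM44 lay in a stretch of 15.88 Mb, from 6,410,001 to 22,290,000, in which MCF7 had 185 loops, T47D 89 and MDA134 33. Loss of a segment and a lack of acetylated chromatin in it cannot be told apart, because bins without a loop have no listed coverage, and 25 other stretches of the SUM44 list were at least as long.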
